A study of Drosophila melanogaster with 2 samples.

How the data were processed

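Chromatin immunoprecipitation followed by sequencing was performed on whole Drosophila melanogaster embryos of 0 to 24 h, with both sexes pooled, from a transgenic line in which ADD1 carries GFP at its C terminus. Per the labels, the precipitation used an anti-GFP antibody, chromatin was sheared by sonication and the size range was 200 to 800 bp. The series holds 1 group with 2 biological replicates, numbered as in the labels. A single line was the source of both, so the results speak for this line only. The p-value of the overlap between the replicate lists compares it with summits shifted along the arms. It does not measure the spread between replicates. No second condition exists, and the control that entered peak calling was not analysed here.

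Peak lists of 3 kinds were used, 4 lists in all, on assembly dm6 per the file headers and descriptions: 1 list per replicate, 1 list called on both alignments together, and 1 list that passed the authors' threshold on the irreproducible discovery rate (IDR). Per the deposited descriptions, each replicate list was derived from that replicate's alignment and a control, and the IDR list from the other lists. The peak caller, its version, the aligner and the read filters are not given in the sources used here, and neither is the number of reads, so the depth of each replicate is unknown. The signal of each peak is the authors' deposited value, on a scale that was not stated, and it was used only within a list, to rank peaks and to compare the medians of promoter and other peaks. The −log10 q-value of each peak is also the authors' deposited value. It was capped at 1 highest value per list, which 6739 of the 7944 IDR peaks shared at 4.13, so it was not used for ranking. Each replicate list and the joint list held exactly 30000 peaks, so their length is no measure of binding. The IDR list was identical to the 7944 peaks of highest signal in the joint list. No list held a peak on the Y chromosome or on unplaced scaffolds, and 0 peaks ran past the end of a reference sequence.

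Genes, transcription starts, exons, mobile elements and sequence were taken from genome Release 6 with FlyBase annotation release 6.54, which is the build of the peak coordinates. Summits were assigned to 1 of 7 classes in a fixed order, with a promoter defined as 500 bp on either side of any annotated start. Expected shares came from 100000 circular shifts of all summits within each arm, which keep the spacing between peaks, and 10000 shifts were used for alternatives. The p-values from shifts are permutation p-values, two-sided except for the overlap of the replicates, and the smallest they can give is 1e-05 one-sided and 2e-05 two-sided. Counts per chromosome arm were compared with the share of ungapped sequence by exact binomial tests, which treat peaks as independent. Gene lists were compared with the other genes by Fisher's exact test, two-sided. Protein-coding lists were set against protein-coding genes on 6 arms, and lists of RNA genes against all genes there. The dosage compensation list mixes both kinds and was set against all genes, and the heat shock list counts its protein-coding members only. The share of peaks with a binding word within 100 bp of the summit was compared with windows of the same size centred 500 bp to each side. The exact binomial test used the peaks in which only the centre or only the flank at lower genome coordinates held the word. The strand of nearby genes was not considered. Adjusted p-values are Benjamini-Hochberg values over 7 arms, 7 classes, 23 lists or 11 words. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

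The gene lists, the words, the tests and the alternatives were fixed before the data were examined. Names in a list that the annotation does not hold were left out, between 0 and 5 per list. Genes were named by a fixed rule: the gene at each of the 25 peaks of highest signal, the up to 3 members of each list with the strongest promoter peak, the 5 strongest peaks of chromosome 4, and ADD1, the gene encoding HP1a, Su(var)3-9, XNP and egg in any case. Further members of the insulator, germ line, muscle, neural and gut lists were named after their values had been seen. A peak with no start within 500 bp was named by the gene that contains it, or else by the nearest start. The alternatives were each replicate alone (its 7944 strongest peaks), the stronger 3972 IDR peaks, the joint list, promoters of 200 or 1000 bp, 50 bp around the summit for words and for matching the replicates, any overlap of at least 1 bp, soft-masked sequence or overlapping intervals in place of summits in annotated elements, windows of 30% soft-masked sequence, genes without another start within 1000 bp, and random summits outside soft-masked sequence. Leaving Y out, counting a summit only for the nearest start, class shares among summits outside promoters, and leaving out 24 paralogs of oxidative phosphorylation genes (symbols ending in L or in L and a number, except ND-MNLL) were added after the data had been seen.

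Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures used matplotlib 3.10.9. The calculations were tested on simulated data. In 20 sets of 4000 random summits the mean promoter fold was 1.01, and 1 of 140 feature tests, 3 of 120 arm tests and 2 of 460 list tests passed the threshold, as did 0 of 120 tests of classes outside promoters. A planted promoter share of 39.5% was recovered as 39.4%, 25 planted genes of the proteasome list were all recovered, and lists built to share 60% of summits gave 60.6%.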

Results

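Binding of ADD1 was profiled in whole embryos of Drosophila melanogaster aged 0 to 24 h. ADD1 is a chromatin protein with an ADD domain that is known to interact with the heterochromatin protein HP1a. The tagged protein was precipitated with an antibody against GFP in 2 biological replicates of 1 group. The only comparison between samples is therefore that of the replicates, and the other comparisons ask where in the genome the peaks lay. The list that passed the authors' reproducibility threshold (IDR) held 7944 summits in 7904 distinct intervals with a median width of 231 bp. The authors' signal ranged from 130 to 9003 in it, with a median of 243. The sequencing depth of the replicates was unknown.

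The replicates placed their strongest peaks at the same sites far more often than shifted peaks did. Of the 7944 strongest summits of replicate 1, 71.8% lay within 200 bp of one of the 7944 strongest summits of replicate 2, and 71.6% the other way round. Circular shifts gave 2.38%, so the overlap was 30.2 times the shifted value (permutation p = 1e-05, the smallest the shifts can give). Of the 250 strongest peaks of replicate 1, 99.2% had a summit within 200 bp anywhere in the list of replicate 2, and 98.0% in the opposite direction. The IDR list was itself derived from the replicate lists and is no separate measure of their overlap, and 70.9% of its peaks were among the 7944 strongest of each replicate. Both whole replicate lists held a summit within 200 bp for 96.4% of the IDR peaks (7659), and each remaining peak had one in a single replicate only. Among genes named below, the peaks at snoRNA:Or-CD11a, Obp99b, Prosbeta7 and GATAe had none in replicate 1. No interval with its signal was identical between the replicate lists.

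**Figure D1:**
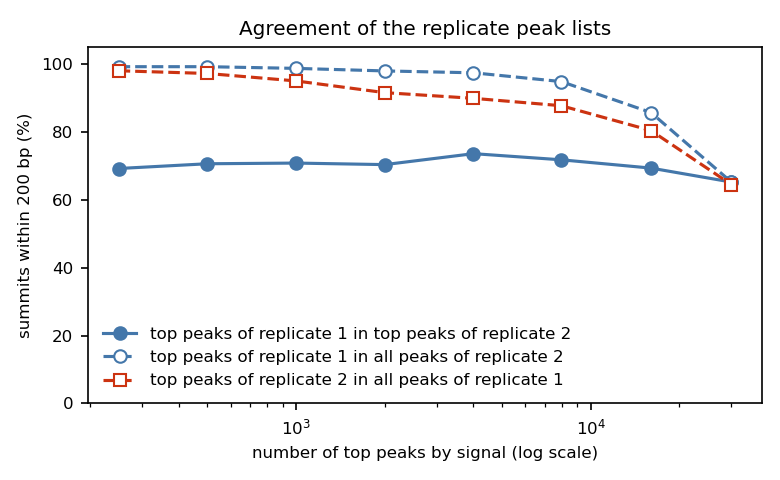
Share of the strongest peaks of one replicate with a summit of the other replicate within 200 bp (vertical axis, %) against the number of peaks taken by signal (horizontal axis, log scale). Filled circles compare replicate 1 with an equal number of peaks of replicate 2 and stay between 65.2% and 73.6%, and open symbols compare with the whole other list and start at 99.2% for replicate 1 and 98.0% for replicate 2.

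All of the 25 strongest peaks were among the 100 strongest of both replicates. A start lay within 500 bp of the summit in 17 of them, 6 lay inside a gene further from a start, and 8 were on the X chromosome. Of all IDR peaks 18.7% were on X, and the count of 8 was not tested. The strongest peak (2L, 13835254 to 13835741, signal 9003) had its summit 104 bp from a start of CenG1A, and a start of mRpS23, a protein of the mitochondrial ribosome, was also within 500 bp. The next lay 44 bp from a start of Ugalt, a UDP-galactose transporter (X, 2703717 to 2704092, signal 8713), and in an intron of CG11050 (2L, 6612389 to 6613008, signal 7816). A peak in an intron of ph-p, which encodes the Polycomb group protein Polyhomeotic, ranked 7 (X, 2136983 to 2138140, signal 5816). Its summit was 506 bp from the nearest ph-p start. A peak 99 bp from a start of Chro, which encodes the chromatin protein Chromator, ranked 24 (3L, 22878657 to 22879089, signal 3666). The other named genes at these peaks were CG1888, asRNA:CR45928 (inside ytr, with a start of eIF6 within 500 bp), CG9663, Lk6, CG14100, MFS10, amon, CG9147, moody, CG17896, lncRNA:CR31840, CG8320, CG3726, Atf3, PNPase, norpA, Mnat9, px, tank and lncRNA:CR45643.

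Peaks were concentrated at promoters and were rare in coding exons. A summit lay within 500 bp of an annotated start in 49.1% of IDR peaks (3902 peaks, exact 95% interval 48.0 to 50.2), against 13.5% of shifted peaks. The promoter share was 3.63 times the shifted value (permutation p = 2e-05, the smallest the shifts can give). It was 47.7% in replicate 1 and 53.1% in replicate 2 (50.4% ± 3.80, SD, n = 2), so the excess over shifted peaks exceeded the spread between replicates. Coding exons held 0.554% of summits (0.0422 times the shifted share), 3' UTRs 1.36% (0.268 times), intergenic sequence 12.6% (0.462 times) and introns 34.6% (0.878 times), each with an adjusted permutation p of 2.8e-05. Each summit counts in 1 class only, so the high promoter share lowers the others. Among the 4042 summits outside promoters, counted so after the data had been seen, introns held 68.0% against 45.6% of shifted summits (1.49 times), and coding exons (0.0718 times), 3' UTRs (0.456 times) and intergenic sequence (0.786 times) held fewer than shifted summits. The 5' UTRs (1.79 times) and noncoding exons (1.96 times) held more (adjusted permutation p = 0.0002 for each of these 6, the smallest 10000 shifts can give). Over all summits the shares in 5' UTRs (0.818%, adjusted permutation p = 0.738) and in noncoding exons (0.919%, adjusted permutation p = 0.391) did not pass the test. Of the 3627 summits within 500 bp of a protein-coding start, 68.7% lay upstream of it, at a median position of -37 bp with quartiles of -103 and 14 bp.

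**Figure D2:**
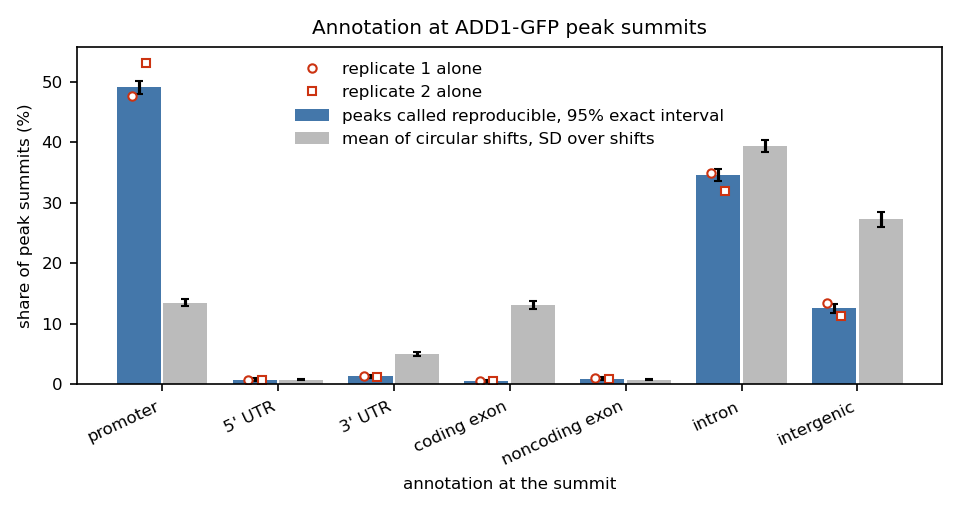
Share of summits (vertical axis, %) in each annotation class (horizontal axis) for the IDR peaks (blue, exact 95% interval), the mean of the circular shifts (grey, SD over shifts) and the 7944 strongest peaks of each replicate (red symbols). Promoters held 49.1% of the summits against 13.5% after shifts, and coding exons 0.554%.

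Promoter peaks had the higher median signal within the list, at 284 against 214 for the other peaks (permutation p = 1e-05, the smallest possible). The ratio of these medians was 1.32, on a scale that was not stated, and it was 1.28 with replicate 1 alone, 1.24 with replicate 2 alone and 1.07 in the stronger 3972 peaks. The promoter share fell over 5 equal parts of the list ordered by signal, from 60.1% in the strongest part through 58.5, 48.6 and 41.5% to 36.8% in the weakest.

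A promoter peak was found at 3638 of 13921 protein-coding genes (26.1%), at 3595 in replicate 1, at 4034 in replicate 2 and at 3039 in each of them. Genes whose start faces away from a neighbouring start on the other strand within 1000 bp had a peak more often. Of 5507 such genes 36.1% had one, against 19.6% of 8414 other genes, which is 1.84 times as many (Fisher's exact p = 5.53e-103). One summit can count for both neighbours, so the genes are not independent in this test. A gene counted as divergent, or as having a peak, if any of its starts did. Genes with more starts can therefore score higher on both, and the number of starts was not matched. The ratio was 1.30 when each summit was counted only for the nearest start (Fisher's exact p = 1.12e-15), again without matching the number of starts.

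The cytoplasmic ribosomal protein genes stood out among the gene lists. A promoter peak was present at 72 of 86 of them (83.7%, exact 95% interval 74.2 to 90.8), against 25.8% of the other coding genes, a ratio of 3.25 (adjusted Fisher's exact p = 1.12e-27). The strongest were at RpS27 (signal 3074, rank 33), RpL7 (2843, rank 42) and RpL14 (2193, rank 68). The share was 83.7% in replicate 1 and 87.2% in replicate 2. The genes of insulator and architectural proteins came next with 15 of 20 (75%, exact 95% interval 50.9 to 91.3, ratio 2.88, adjusted Fisher's exact p = 3.13e-05). This list has peaks at Chro, Trl (the GAGA factor, signal 1497), Dref (749), CTCF, su(Hw), Cp190, mod(mdg4) and BEAF-32, and M1BP, ZIPIC, dwg, SMC3 and Nipped-B had none. Leaving only genes with no other start within 1000 bp reduced it to 2 members, 0 of which had a peak.

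Mitochondrial ribosomal protein genes (31 of 73, 42.5%, ratio 1.63, adjusted Fisher's exact p = 0.00961) and oxidative phosphorylation genes (35 of 88, 39.8%, ratio 1.53, adjusted Fisher's exact p = 0.0141) were bound more often than other genes. Neither call held when only genes with no other start within 1000 bp were kept (ratios 0.398 and 1.00). The first did not pass with promoters of 200 bp (ratio 1.45, adjusted Fisher's exact p = 0.121). The second did not pass in the stronger 3972 peaks (ratio 1.55, adjusted Fisher's exact p = 0.0556). Neither held when each summit counted only for the nearest start (ratios 0.836 and 1.5, adjusted Fisher's exact p = 0.685 and 0.0536). The oxidative phosphorylation list holds 24 paralogs with names ending in L, 0 of which had a peak, and without them, as chosen after the data had been seen, 35 of 64 had one (54.7%, ratio 2.10, adjusted Fisher's exact p = 5.71e-06). The strongest examples were mRpS23, mRpS10 and mRpL23, and ND-ASHI, ND-MWFE and COX6B. In mRpS23 the summit was 388 bp from the start and nearer to that of CenG1A.

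Peaks were infrequent at genes of the cuticle (2 of 95, Cpr65Av and Cpr73D, adjusted Fisher's exact p = 2.2e-09) and of the chemoreceptors (4 of 230, with Ir60e, Obp99b and Gr63a the strongest, adjusted Fisher's exact p = 1.06e-23). No peak lay at any of the 111 replication-dependent histone genes, which form a repeated array in which reads are shared between copies (adjusted Fisher's exact p = 2.6e-14, and 0.0804 among genes with no other start within 1000 bp). The test counts these copies as independent genes, which they are not, so its p-values overstate the evidence. The snRNA and snoRNA genes had peaks at 39 of 301 (13.0%, adjusted Fisher's exact p = 3.52e-05), with snoRNA:Psi28S-2949, snoRNA:Or-aca5 and snoRNA:Or-CD11a the strongest. The first 2 share 1 summit, 173 and 486 bp from their starts and 74 bp from that of the noncoding gene Uhg4, and the summit of snoRNA:Or-CD11a was 440 bp from its start and 360 bp from that of eIF1. Replicate 1 had no summit within 200 bp of the snoRNA:Or-CD11a summit. With promoters of 1000 bp the ratio of the snRNA and snoRNA genes to other genes was 1.10, and among genes with no other start within 1000 bp 0.998, and neither passed.

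In the IDR list the remaining 15 lists did not pass the test (adjusted Fisher's exact p from 0.0698 to 1). Among genes of heterochromatin proteins 9 of 26 had a peak (34.6%, adjusted Fisher's exact p = 0.568), with ADD1, G9a and wde the strongest. The tagged gene itself had a peak at rank 369 (signal 970), whose summit lay exactly 500 bp from the ADD1 start (2R, 11970686 to 11977721) and therefore dropped out with promoters of 200 bp. The gene encoding HP1a (FBgn0003607, 2L, 8209626 to 8211122) had one 144 bp from its start at rank 3693. The nearest summits to Su(var)3-9, XNP and egg, which encode a histone methyltransferase, a chromatin remodeller and a methyltransferase, were 11830, 7604 and 13754 bp away. Polycomb group genes had peaks at 7 of 19 (jing, Pc and Su(z)12 the strongest, adjusted Fisher's exact p = 0.555), but passed with replicate 1 alone (52.6%, ratio 2.04, adjusted Fisher's exact p = 0.0375). Peaks lay at trithorax group and remodeller genes in 7 of 20 cases (Iswi, brm and Nurf-38, adjusted Fisher's exact p = 0.600). Telomere capping genes had 3 of 12 (eff, ver and pzg) and dosage compensation genes 3 of 8, namely lncRNA:roX2, lncRNA:roX1 and Clamp. The Clamp peak ranked only 12541 in replicate 2.

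Genes of general cell functions gave 11 of 32 for the proteasome (Prosbeta1, Rpn5 and Prosbeta7), 13 of 35 for the cell cycle and replication (Dp, BubR1 and mad2) and 9 of 21 for heat shock proteins (Hsp83, Hsc70-5 and, as a noncoding gene outside this count, lncRNA:Hsromega). With replicate 2 alone the proteasome list (ratio 1.73, adjusted Fisher's exact p = 0.0397) and the Hox and segmentation list (0.313, adjusted Fisher's exact p = 0.0285) passed. Hox and segmentation genes also passed in the stronger 3972 peaks (ratio 0, adjusted Fisher's exact p = 0.00691) and with promoters of 1000 bp (0.307, adjusted Fisher's exact p = 0.0235). They did not pass with replicate 1 alone (0.586, adjusted Fisher's exact p = 0.442), with promoters of 200 bp (0.417, adjusted Fisher's exact p = 0.204), with the nearest start only (0.427, adjusted Fisher's exact p = 0.211) or among genes with no other start within 1000 bp (0.534, adjusted Fisher's exact p = 0.672). Developmental lists gave 3 of 33 for Hox and segmentation genes (wg, cad and hh, 9.09%, adjusted Fisher's exact p = 0.0698), 6 of 22 for early zygotic genes (rho, sog and brk) and 4 of 25 for piRNA pathway and germ line genes (vas, tapas, squ and gcl). The tissue lists gave 5 of 20 for neural genes (elav, Syx1A, futsch, Syt1 and nrv3), 4 of 20 for muscle genes (sls, Tm1, Mef2 and how) and 5 of 17 for gut, fat body, haemocyte and tracheal genes (fkh, GATAe, CrebA, grh and rib). Of 290 tRNA genes 62 had a peak (21.4%, adjusted Fisher's exact p = 0.618), the strongest at tRNA:Tyr-GTA-1-8, tRNA:Phe-GAA-1-2 and tRNA:Ala-TGC-2-1. The tRNA share was below that of other genes in the stronger 3972 peaks (ratio 0.446, adjusted Fisher's exact p = 7.51e-05) and with promoters of 200 bp (0.643, adjusted Fisher's exact p = 0.00970).

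**Figure D3:**
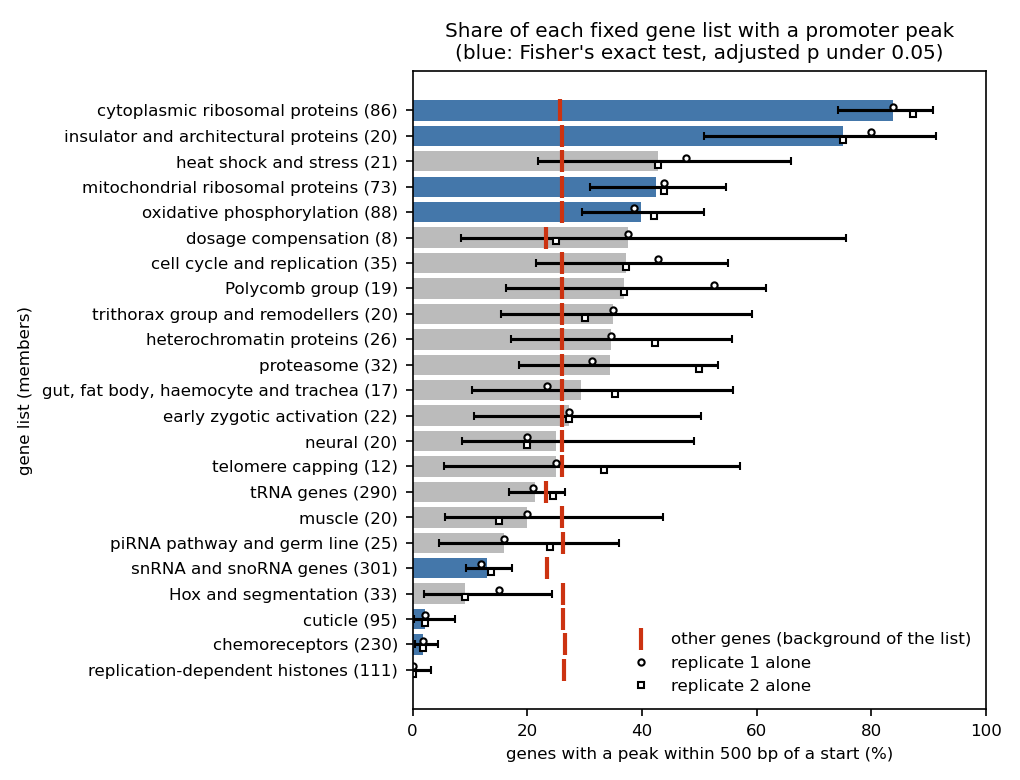
Share of the genes of each list with a peak within 500 bp of a start (horizontal axis, %, bars with exact 95% intervals, blue where the adjusted p of Fisher's exact test passed 0.05), the share among the other genes of the same background (red marks) and in each replicate alone (symbols), with the lists and their number of members on the vertical axis. Ribosomal protein genes stand at 83.7% and insulator genes at 75%, and chemoreceptor genes at 1.74%.

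Peaks were spread over the 6 arms other than Y in rough proportion to sequence, with small differences. The X chromosome held 63.3 peaks per Mb (1.09 times its share of the sequence, adjusted exact binomial p = 0.000871) and 3R 54.7 per Mb (0.944 times, adjusted exact binomial p = 0.0126). These shares count Y, on which no list held a peak, and without Y, as chosen after the data had been seen, X was at 1.06 (adjusted exact binomial p = 0.0260) and 3R at 0.920 (adjusted exact binomial p = 0.000347). With replicate 1 alone X was at 1.05 and 3R at 0.962, and neither passed, and with replicate 2 alone 3R did not pass at 0.957. Densities on 2L, 2R and 3L were 60.7, 60.1 and 60.3 per Mb and did not pass the test, but 2R passed with replicate 2 alone (1.07 times, adjusted exact binomial p = 0.00458). The small chromosome 4, which is largely heterochromatic, held 72 peaks or 54.1 per Mb (0.933 times, adjusted exact binomial p = 0.606), at 60.9 per Mb in replicate 1 and 46.6 in replicate 2. Its 5 strongest peaks lay 3909 bp from a start of zfh2 and at starts of RpS3A, asRNA:CR43957, Gyf and Arl4, with signals from 958 down to 763.

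Annotated mobile elements and repeat-rich windows held few peaks, and soft-masked sequence as a whole held a larger number. Mobile elements contained 18 summits (0.227%, exact 95% interval 0.134 to 0.358) against 5.43% of shifted peaks, 0.0417 times as many (permutation p = 2e-05, the smallest possible). The ratio was 0.118 when any overlap of a peak interval with an element counted. In soft-masked sequence of any kind 915 summits were found (11.5% against 20.1%, 0.573 times, permutation p = 0.0002, the smallest 10000 shifts can give). In 22 windows of 100 kb on the major arms with at least 50% soft-masked sequence, a stand-in for pericentric heterochromatin that covers 2.05 Mb, 12 of 7872 summits were found (0.152% against 1.54%, 0.0993 times, permutation p = 6e-05). In the 173 windows with at least 30% soft-masked sequence, which cover 17.1 Mb, 151 summits were found (1.92% against 12.8%, 0.15 times, permutation p = 0.0002, the smallest 10000 shifts can give). Reads from repeated sequence are under-represented wherever only uniquely placed reads are kept, and the read filters are not given in the sources used here.

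Words bound by insulator and promoter proteins were enriched at peak centres, and their shares differed between promoter and other peaks. TATCGATA, the site of DREF and BEAF-32, occurred within 100 bp of 4.24% of summits (4.46 times the flanks, adjusted exact binomial p = 2.34e-42), and GGTCACACT, the site of M1BP, in 2.76% (5.76 times, adjusted exact binomial p = 3.13e-35). TATCGATA stood at 7.89% of promoter peaks and 0.717% of the others (odds ratio 11.9, adjusted Fisher's exact p = 1.07e-63), and GGTCACACT at 5.25% and 0.346% (odds ratio 16.0, adjusted Fisher's exact p = 1.09e-46). The Su(Hw) word GCATACTTT went the other way, at 1.81% of other peaks and 0.564% of promoter peaks (odds ratio 0.308, adjusted Fisher's exact p = 6.51e-07). The CTCF word AGGTGGCGC did so too, at 0.990% and 0.513% (odds ratio 0.515, adjusted Fisher's exact p = 0.0297). Over all peaks these words were 3.17 and 4.0 times as frequent at centres as at flanks. At other peaks they stood at 5.21 and 5.71 times the flanks (adjusted exact binomial p = 2.34e-09 and 5.58e-05). The CTCF word was also enriched at promoter peaks (2.5 times, adjusted exact binomial p = 0.0491). There the Su(Hw) word, at 1.38 times, did not pass (adjusted exact binomial p = 0.575).

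Over all peaks GAGAGAG, the word of the GAGA factor and CLAMP, was 1.40 times and the E-box CAGCTG 1.33 times as frequent as in flanks (adjusted exact binomial p = 4.53e-07 and 2.72e-07). At promoter peaks they stood at 1.72 and 1.48 times the flanks (adjusted exact binomial p = 7.66e-09 and 1.06e-08). At other peaks both were at 1.13 and did not pass (adjusted exact binomial p = 0.355 for each). Neither the Zelda word CAGGTAG (0.817 times, adjusted exact binomial p = 0.269) nor CACGTG (0.929 times, adjusted exact binomial p = 0.805) passed the test over all peaks. At promoter peaks CAGGTAG was depleted (0.558 times, adjusted exact binomial p = 0.00854). AAAAAAAA and TATAAA were depleted, at 0.441 and 0.876 times the flanks (adjusted exact binomial p = 1.97e-58 and 2.12e-06). CACACACA was 1.15 times as frequent over all peaks (adjusted exact binomial p = 0.0100). It was at 1.36 at other peaks (adjusted exact binomial p = 0.00018) and at 0.970 at promoter peaks, where it did not pass (adjusted exact binomial p = 0.786). The calls of TATAAA and CACACACA over all peaks did not hold with replicate 1 alone or in the stronger 3972 peaks. That of GAGAGAG over all peaks did not hold in those 3972 peaks or within 50 bp of the summit. CACGTG was at 1.20 and passed with replicate 2 alone.

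**Figure D4:**
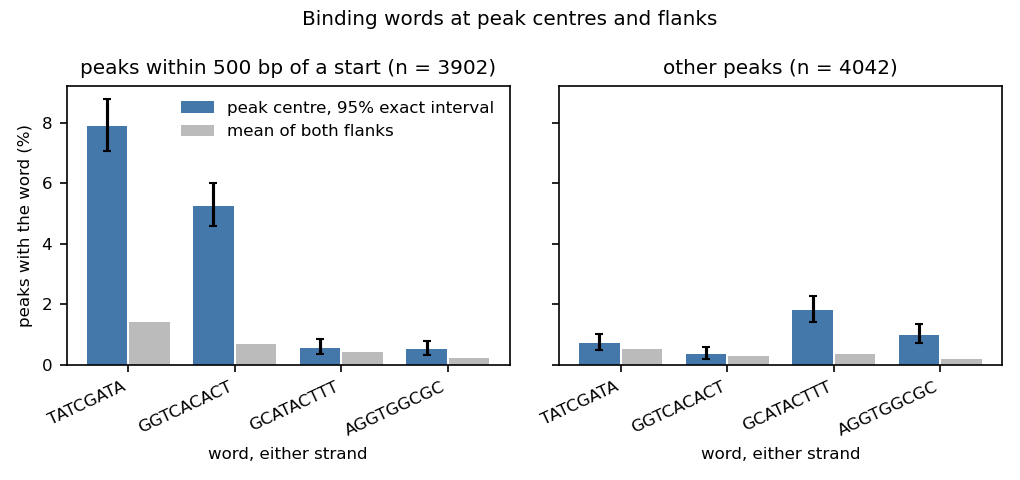
Share of peaks with each of 4 words within 100 bp of the summit (blue, exact 95% interval) and the mean of the flanking windows (grey), on a common vertical axis (%), for 3902 promoter peaks on the left and 4042 other peaks on the right. TATCGATA and GGTCACACT reach 7.89% and 5.25% at promoter peaks, and GCATACTTT 1.81% at other peaks.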

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

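The tests that counted a summit only for the nearest start, those without Y, those of summits outside promoters and those without 24 paralogs of oxidative phosphorylation genes were chosen after the data had been seen. Of 399 values recomputed under alternatives, 342 kept their direction and their side of the threshold (counts of calls: stayed within 1.5 times), 14 no longer passed, 12 newly passed, 29 changed direction and 2 counts moved. Ratios for promoters (2.55 to 6.53), mobile elements (0.0276 to 0.118), divergent starts (1.30 to 2.10), ribosomal protein genes (3.03 to 4.43), TATCGATA (4.44 to 5.65) and GGTCACACT (5.63 to 6.17) kept both throughout. Soft-masked sequence in place of annotated elements stood at 0.573 and kept both too. The strongest 7944 peaks of the joint list are the IDR list, so that alternative moves nothing, and its 56 values are among the 342 by construction. With either replicate left out, the arms past the threshold ranged from 1 to 3 with Y, which passed in each and was the only one with replicate 1 alone, and ratios from 1.04 to 1.07 for 2R (which passed with replicate 2 alone), 0.957 to 0.962 for 3R, 1.05 to 1.08 for X, 0.804 to 1.05 for chromosome 4, 0.971 to 1.05 for 5' UTRs, 0.968 to 1.15 for telomere capping, 0.976 to 1.63 for dosage compensation, 0.941 to 1.06 for early zygotic genes, 0.911 to 1.22 for the gut list, 1.21 to 1.73 for the proteasome, 0.313 to 0.586 for Hox and segmentation, 1.27 to 2.04 for Polycomb, 0.911 to 1.20 for CACGTG, 0.747 to 0.963 for TATAAA and 1.03 to 1.33 for CACACACA. In the stronger 3972 peaks, 2L (1.08), Hox and segmentation (0) and tRNA genes (0.446) newly passed, and oxidative phosphorylation (1.55), GAGAGAG (1.24) and TATAAA (0.951) no longer did. Direction changed there for 3L (0.971), chromosome 4 (1.09), 5' UTRs (0.969), noncoding exons (0.918), telomere capping (1.41), early zygotic genes (0.513), the gut list (0.332), CACGTG (1.03) and CACACACA (0.959). Among summits outside promoters 5' UTRs (1.79) and noncoding exons (1.96) passed and introns changed direction (1.49), since the promoter share no longer lowers the others. With 200 bp promoters noncoding exons (1.30) and tRNA genes (0.643) passed and the mitochondrial ribosomal list (1.45) did not. With 1000 bp Hox and segmentation passed (0.307), and 5' UTRs (0.536), the gut list (0.995) and snRNA and snoRNA genes (1.10) changed direction. Within 50 bp of the summit GAGAGAG (1.13) did not pass and CACACACA changed direction (0.948). Among genes with no other start within 1000 bp, where lists are smaller, 3 lists passed in place of 8. Oxidative phosphorylation (1.00), histones (0) and snRNA and snoRNA genes (0.998) did not pass, and the insulator (0), mitochondrial ribosomal (0.398), heterochromatin (0.739), heat shock (0.647) and neural (1.29) lists changed direction. With the nearest start only, oxidative phosphorylation (1.5) did not pass, and the mitochondrial ribosomal (0.836), heterochromatin (0.723) and neural (1.18) lists changed direction. The promoter share lowers the other classes by construction, and the causes of the other changes, smaller lists among them, were not tested. No paired analysis was possible because there is only 1 group. The depth is unknown, which limits how far weak peaks and the weight of each replicate can be judged.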

Other observations

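The tests of ribosomal protein genes against other housekeeping lists and against tRNA genes, and those of intron summits, further translation genes and words of 8 bases, were chosen after the results had been seen. The other tests were written down before their values were computed.

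Summits inside introns lay closer to starts than shifted summits did. Of 2750 intron summits, all further than 500 bp from a start, 1176 (42.8%) were within 2000 bp of one, against 21.7% of shifted summits in introns (1.97 times, permutation p = 0.0002, the smallest 10000 shifts can give). Among further translation genes no family passed the test against other coding genes. Of these, 17 of 44 initiation factor genes had a promoter peak (eIF6, eIF1 and eIF2A the strongest, adjusted Fisher's exact p = 0.125), 4 of 8 elongation factor genes (eEF1gamma, eEF1alpha1 and eEF5, adjusted Fisher's exact p = 0.219) and 3 of 32 aminoacyl-tRNA synthetase genes (SerRS, ArgRS-m and HisRS, adjusted Fisher's exact p = 0.0816). A search of all words of 8 bases on 2L, 2R and 4 returned mainly parts of the DREF and M1BP sites, and also CAACACTG and AACAGCTG. Counted on 3L, 3R and X, CAACACTG stood within 50 bp of 1.71% of 4926 summits against 0.305% of flanks (5.60 times, adjusted exact binomial p = 2.25e-11), and AACAGCTG at 2.27% against 0.985% (2.31 times, adjusted exact binomial p = 6.94e-06). The counted arms were not untouched data, because CAACACTG had already been seen in a search of all arms.

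Few peaks lay in repeat-rich windows and mobile elements, although ADD1 is known as a partner of HP1a. Unique sequence was defined as positions at which at least 80% of the 36-base words within 150 bp occur once in the assembly, and it made up 10.8% of the repeat-rich windows and 85.7% of the 6 arms. Within it, peak density in repeat-rich windows was 0.820 of that elsewhere (exact 95% interval 0.423 to 1.43), up from 0.102 over all sequence, so reads that cannot be placed uniquely may account for the low number there. The windows also hold few genes, and promoter peaks per annotated start were 1.63 times those elsewhere (exact 95% interval 0.743 to 3.09, 9 peaks and 33 starts), so a lack of starts remains a candidate explanation too. Inside mobile elements the density was still 0.184 of that outside in unique sequence (exact 95% interval 0.105 to 0.299). This argues against unplaced reads as the whole cause there, as far as the definition captures them. Only 17.2% of element sequence was unique by it. Positions that pass the 80% limit can still hold repeated words, and their share was not compared between elements and the rest. A lack of starts inside mobile elements was not tested, and neither was a biological explanation.

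Ribosomal protein genes had a promoter peak in 83.7% of cases. Random coding genes matched on the number of starts and on divergent neighbours reached a mean of 35.6% and at most 55.8% in 10000 draws. This argues against those matched features as the whole cause. Other promoter features, the DREF and M1BP words among them, were not matched. The proteasome, mitochondrial ribosomal and oxidative phosphorylation genes together stood at 39.9% (77 of 193, Fisher's exact p = 4.35e-12), and at 45.6% (77 of 169, Fisher's exact p = 2.08e-09) without 24 paralogs of oxidative phosphorylation genes, which argues against a frequency shared with these 3 lists and leaves other housekeeping genes untested. Precipitated signal at strongly transcribed genes, whatever the tagged protein, may still contribute: tRNA genes with unique flanks stood at 21.9% against 23.9% of other genes (Fisher's exact p = 0.482), and all tRNA genes stood at 0.446 times other genes in the stronger 3972 peaks, but they are read by another polymerase, and neither expression values nor a precipitation of untagged embryos was analysed here.

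The words at promoter peaks could simply be those of promoters. Among coding genes without a peak 11.5% had TATCGATA or GGTCACACT within 100 bp of a start, against 20.3% of genes with one (odds ratio 1.97, Fisher's exact p = 8.72e-38). A gene counted for the word or the peak if any of its starts did, and the number of starts was not matched. Genes with more starts can therefore score higher on both, so promoters in general stay open as a cause. At the 4042 other peaks, 110 centres held the Su(Hw) or CTCF word, while shuffles that keep the dinucleotides gave a mean of 14.5 and at most 27 in 1000 draws (permutation p = 0.001, the smallest they can give), which argues against base composition. Open chromatin at these sites in general was not tested and stays open.

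Extra copies of the tagged locus would raise signal around ADD1. The joint list held 6 peaks within 20 kb of ADD1, against a median of 10 around coding genes, of which 31.8% had fewer. This number is ordinary, and peaks called against a control measure an even rise in signal poorly, so extra copies stay open.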
